A study of Mus musculus with 8 samples.

How the data were processed

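Expression was profiled with 8 one-colour Cy3 arrays of Agilent mouse design 028005, 2 arrays in each of 4 groups: parental N18TG2 untreated, parental with RA, 2/4 clone untreated and 2/4 clone with RA. Per the labels, RA was given at 1 µM in medium with 1% serum, growth medium held 10% serum, and the clone was kept in G418 at 200 µg/mL. The labels give neither the length of RA treatment nor the medium of the untreated cells, so serum may go with RA, and G418 selection goes with the clone. The extraction protocol in the labels names hippocampus although the samples are a cell line, so markers of hippocampal neurons and other cell types were tested. Nothing in the labels says that the arrays of a group came from separate cultures, and if they did not, the p-values measure only the spread between samples of a culture.

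The intensity values were background-subtracted and detrended within each array by Feature Extraction 10.7.3.1, per the file headers, with no scaling between arrays. The deposited log2 values of the series table equalled the log2 of that intensity minus 1 constant per array that places the 75th percentile near 0, which was checked against the scanner tables. For probes with 1 spot they differed from the scaling used here by a constant of 0.154 to 0.261 per array and departed from it by at most 1.95e-06, and their 75th percentile lay at 0.0049 to 0.00829. All arrays lay on 1 slide with 1 scan time. Row 1 of the slide held the parental RA and untreated clone arrays, and row 2 the parental untreated and clone RA arrays, so slide row goes with RA within each line, with the line within each treatment and with the interaction. It cancels only in the averages.

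From the scanner tables, log2 of the background-subtracted intensity was taken minus its 75th percentile over non-control spots. Of 62976 spots per array, 3671 were controls and were left out. Spots that Feature Extraction marked as outliers were also left out, a choice not fixed beforehand, and spots of a probe were averaged. Of 55681 probes, 36616 were well above background on at least 2 of 8 arrays and were kept. The brightest probe represented each gene, which gave 26247 features, called genes here, of which 15169 carried a symbol through RefSeq accessions and 11078 did not. No coordinates were used. Signal over background limits the dim end, and the array clone RA replicate 1 held 42774 spots well above background against 28849 to 37529 on the others.

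A linear model with 1 mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3, with moderated t-tests on 4 residual and 3 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were clone against parental without RA and with RA, RA against untreated in each line, the interaction, and both averages. Gene lists, 30 fixed in advance with 716 tested entries, were tested with limma's camera at a preset correlation of 0.01 between genes. With the correlation estimated from the data, 0 lists were called in each comparison, so list calls hold only under the preset value. The fry test, tried as an alternative, asks whether the genes of a set move on balance one way and does not compare them with other genes. Where a gene was not well above background on any array of a group, only a bound is given, the fold from the lowest level well above background there ("at least").

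The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Chat and Lmna always. It adds the called genes with the largest changes that were above background on all arrays compared, those with the largest bounds, and up to 4 members with the smallest adjusted p from each list that was called or had 3 called members. A gene counted as above background if any of its probes was; a reading by the chosen probe alone was tried after values were seen and was given up. Alternatives were normexp background correction, quantile normalization, the series table values, no filter and a stricter filter on dim probes, a floor for dim signals, the mean of a gene's probes, a trended and robust variance, only the groups compared, the side of the slide as a block, a 2-fold threshold, and leaving out each array. Normexp was run on the median spot signal, a change made after the data were seen because the tables hold no mean signal.

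The fit was tested on simulated data for 26195 genes, of which 67, 67 and 66 were changed by log2 1, 2 and 3. Of changes set at log2 1, 2 and 3, it recovered 0%, 26.9% and 84.8% for clone against parental without RA, 0%, 25.4% and 81.8% for RA in the clone, 4.48%, 74.6% and 92.4% for the average clone effect and 0%, 70.1% and 92.4% for the average RA effect. For the interaction it recovered 0% at each size. The smallest interaction called in the data was log2 3.07, so most differences of the simulated sizes between RA responses would be missed. With so few changed genes the adjusted p is stricter than where many genes change. The recovery rates are therefore not the sensitivity of each comparison, and the average clone effect was called down to log2 0.579 in the data. Other tools were data.table version 1.17.8, Python 3.11.15 and matplotlib 3.10.9.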

Results

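Gene expression was measured on 8 one-colour microarrays in N18TG2, a mouse neuroblastoma line, and in the 2/4 clone, a line that the labels describe as expressing choline acetyltransferase (ChAT), the enzyme that makes acetylcholine. Each line was profiled untreated and after all-trans retinoic acid (RA) at 1 µM, a vitamin A derivative widely used to differentiate neuroblastoma cells, with 2 arrays in each of the 4 groups. The title of the series names ChAT and lamin A/C, a protein of the nuclear lamina encoded by Lmna. The 75th percentile of the background-subtracted intensity ran from 264.8 to 1264 over the arrays. On 7 arrays, 47.74% to 62.76% of probes were well above background, against 71.7% on the array clone RA replicate 1. That array was also the only one that the scanner software marked for evaluation, with a spike-in detection limit of 2.11 outside the software's range, and the clone RA pair had the lowest replicate correlation (r = 0.9625 across genes, against 0.983 to 0.9872 in the other 3 pairs). The first principal component held 52.44% of the variance and placed the 4 parental and the 4 clone arrays on opposite sides. Correlations of arrays overlapped, with the lowest within a line at 0.9487 and the highest between the lines at 0.9505.

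Lmna read higher in the untreated clone than in the untreated parental line, and lower in the clone with RA than without. Slide row goes with both comparisons, and serum may go with RA, so their part in these differences cannot be told apart. The untreated clone had 2.42-fold more Lmna signal, a log2 difference of 1.27 ± 0.26 (standard error, n = 2 arrays per group, limma adjusted p = 0.0254). Mean log2 scaled intensity was 5.01 ± 0.22 (SD) in the clone and 3.74 ± 0.08 in the parental line. With RA, Lmna in the clone was 2.82-fold lower (log2 -1.50 ± 0.26, adjusted p = 0.0307) and stood at 3.52 ± 0.02, while the parental difference was -0.34 ± 0.26 (adjusted p = 0.642). Under RA the lines differed by 0.12 ± 0.26 (adjusted p = 0.766). The test of the difference between both RA responses gave -1.15 ± 0.37 (adjusted p = 0.232), so a line-specific Lmna response was not shown. The untreated Lmna difference lay between 1.12 and 1.43 without any 1 of the 4 untreated arrays, with adjusted p from 0.0929 to 0.189, and its adjusted p was 0.0794 with no filter on dim probes. The Lmna call with RA in the clone ended with normexp background correction (adjusted p = 0.0527), with no filter (0.103) and with only the clone groups fitted (0.11). It also ended without clone untreated replicate 1 (0.148) or 2 (0.224), parental untreated replicate 1 or 2 (0.0684 each) or clone RA replicate 1 (0.0861).

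Chat, the gene of the enzyme that the labels say the clone expresses, was read by 1 probe, which was well above background on all 8 arrays but spread widely within groups. The untreated clone exceeded the untreated parental line by a log2 difference of 0.38 ± 1.27 (n = 2 arrays per group, adjusted p = 0.897), with a 95% interval from -2.62 to 3.38, so this probe left the label of the untreated clone open. Under RA the clone exceeded the parental line by 3.40 ± 1.27 (adjusted p = 0.0995). The RA differences were -0.54 ± 1.27 in the parental line (adjusted p = 0.911) and 2.48 ± 1.27 in the clone (adjusted p = 0.312). The array clone RA replicate 1 read 1.10 and clone RA replicate 2 read -2.58, so the Chat values under RA rested on that array. Without clone RA replicate 1, the clone exceeded the parental line under RA by 1.56 (adjusted p = 0.316), and without clone RA replicate 2 by 5.24 (adjusted p = 0.00715). The RA difference of Chat in the clone was 0.64 (adjusted p = 0.78) without replicate 1 and 4.32 (adjusted p = 0.0304) without replicate 2. Under RA, a call between the lines was also reached with only probes above background on all arrays (adjusted p = 0.0448).

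**Figure D1:**
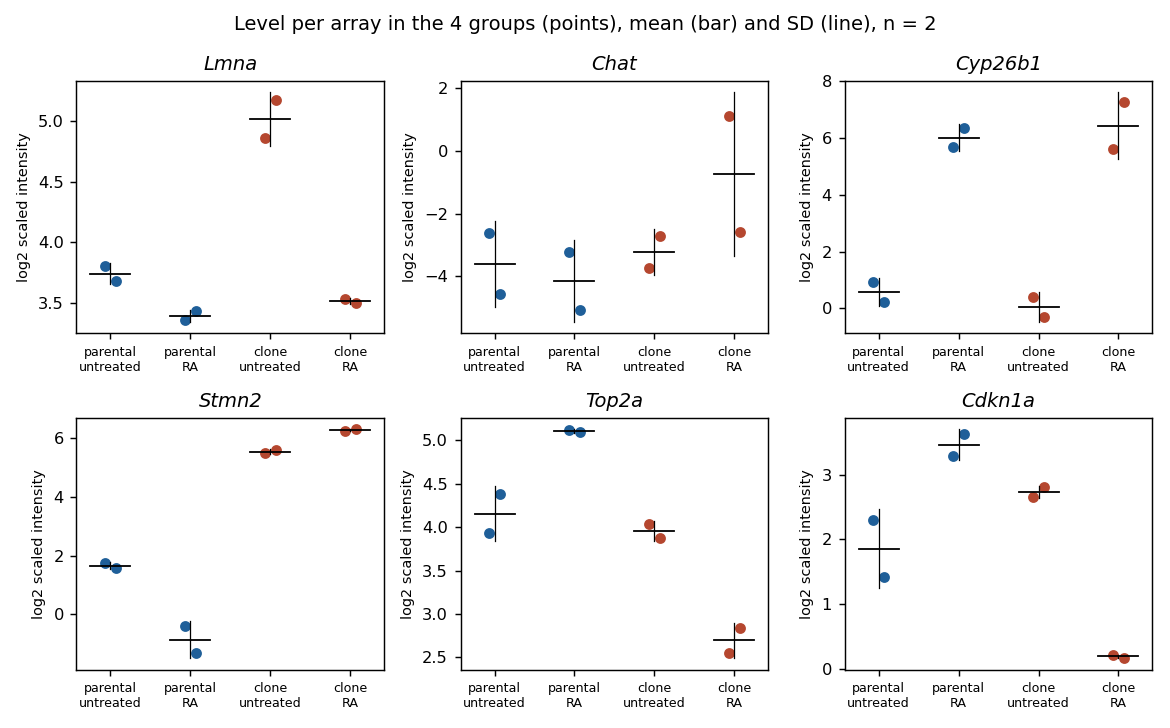
Log2 scaled intensity (y axis) of Lmna, Chat, Cyp26b1, Stmn2, Top2a and Cdkn1a on each array of the 4 groups (x axis); points are arrays, bars are group means and vertical lines are SDs, n = 2. Lmna lay highest in the untreated clone at a mean of 5.01, and the Chat arrays of the clone with RA read 1.10 and -2.58.

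The comparison of the untreated lines asks which genes set the 2/4 clone apart without RA. The untreated groups lay in different slide rows, and under RA the rows of the lines were swapped. Slit1, a secreted axon guidance ligand, was 114-fold higher (log2 6.83 ± 0.26, n = 2 arrays per group, adjusted p = 8.41e-05), Stmn2, a microtubule regulator of growth cones, 14.7-fold (3.88 ± 0.35, adjusted p = 0.000926), and Gap43, a growth cone membrane protein, 3.86-fold (1.95 ± 0.31, adjusted p = 0.0097). The axon guidance list that holds Slit1 had 7 higher and 0 lower of 24 (8 and 1 adjusted over the list alone) and was not called by camera (adjusted p = 0.0616). Several single genes were much lower. Dlk1, a membrane protein of chromaffin and neuroblastoma cells, was 773-fold lower (log2 -9.60 ± 0.59, adjusted p = 0.00027), Insm1, a zinc finger factor of neuroendocrine differentiation, 318-fold lower (-8.31 ± 0.37, adjusted p = 0.000108), and Dbh, which makes noradrenaline from dopamine, 51.0-fold lower (-5.67 ± 0.43, adjusted p = 0.000497). The adrenergic neuroblast list that holds Dlk1 and Dbh went both ways, with 3 higher and 3 lower of 23 (3 and 5 adjusted over the list alone), and camera gave an adjusted p of 0.316.

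By gene list, the neuronal cytoskeleton and growth cone genes were higher in the untreated clone for 10 of 26 tested members and lower for 0 (17 and 0 adjusted over the list alone), including the neurofilament genes Nefh at 1.51 ± 0.27 and Ina at 1.60 ± 0.30. The camera test of this list gave an adjusted p of 1.18e-05, and an adjusted p of 0.386 with an estimated correlation. Voltage-gated ion channels were higher for 3 of 20 members (6 adjusted over the list alone), among them the sodium channel gene Scn3a at 3.39 ± 0.37 and the calcium channel gene Cacna1h at 2.12 ± 0.32. The list had a camera adjusted p of 0.0099, and adjusted p = 0.386 with an estimated correlation. Synaptic vesicle genes moved both ways, with 7 higher and 2 lower of 29 (11 and 2 adjusted over the list alone). The vesicle protein genes Syn1 and Rab3a were higher by 2.47 ± 0.30 and 2.42 ± 0.27, whereas Rab3b and Vamp1 were at -3.14 ± 0.27 and -3.09 ± 0.27. For this list camera gave adjusted p = 0.0387, and adjusted p = 0.564 with an estimated correlation. Immediate early genes were lower for 6 of 30 members and higher for 1 (9 and 1 adjusted over the list alone), among them the transcription factor genes Maff at -2.15 ± 0.34 and Klf2 at -1.62 ± 0.28. Tested by camera, the list had an adjusted p of 0.00113, and adjusted p = 0.386 with an estimated correlation. Of 18 markers of mesenchymal neuroblasts, 4 were lower, such as the receptor kinase gene Axl at -2.84 ± 0.30 and the transcription factor gene Sox9 at -3.36 ± 0.42 (5 lower adjusted over the list alone). The list had a camera adjusted p of 0.0387, and adjusted p = 0.386 with an estimated correlation. None of the 43 cytosolic ribosomal protein genes passed the test, although camera called their median of -0.344 (adjusted p = 0.00951, and adjusted p = 0.981 with an estimated correlation); that median was -0.0592 under quantile normalization.

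Single members of lists that camera did not call also differed in the untreated clone. Jag1, a Notch ligand, was not well above background in the clone and at least 80.9-fold lower (adjusted p = 0.000473), whereas Dtx1 and Mfng, modifiers of Notch signalling, were higher by 3.86 ± 0.27 and 3.81 ± 0.28. The major histocompatibility genes H2-K1 and H2-D1 were at -4.33 ± 0.31 and -4.04 ± 0.26. The largest differences from background were Steap1, a membrane protein gene, at least 1260-fold lower in the clone, Rpl39l, a ribosomal protein paralogue, at least 1210-fold lower, and Prom1, which encodes the membrane protein CD133, at least 608-fold lower. Lpar4, a lysophosphatidic acid receptor gene, was at least 83.7-fold higher and Col22a1, a collagen gene, at least 57.8-fold higher. Markers of other cell types were not called as lists, with camera adjusted p of 0.582 for Schwann and glial cells, 0.959 for hippocampal neurons, 0.959 for blood vessels and microglia and 0.264 for fibroblasts.

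Across the array, 2582 of 26247 tested genes differed between the untreated lines at a limma adjusted p under 0.05, with 1612 higher and 970 lower in the clone. The count was 1213 with normexp background correction and 1386 with no filter on dim probes. It was 1028 and 786 without clone untreated replicate 1 and 2 and 1028 and 1097 without parental untreated replicate 1 and 2. The number of lists called by camera was 6, and 3 without parental untreated replicate 1. The synaptic vesicle call ended with quantile normalization (adjusted p = 0.059), with the mean of probes (0.0961), and without clone untreated replicate 1 (0.0852), parental untreated replicate 1 (0.0636) or 2 (0.0762) or either clone RA array (0.0574). The ion channel call ended without clone untreated replicate 1 (0.0852). The mesenchymal call ended with the mean of probes (0.0687), with fry (0.0695), and without clone untreated replicate 2 (0.0603) or parental untreated replicate 1 (0.0799), and the ribosomal call with quantile normalization (0.514), with fry (0.571) and without parental untreated replicate 1 (0.496).

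With RA in the parental line, several known targets of RA signalling were higher and several neuronal and matrix genes lower. Slide row goes with this comparison, and serum may as well. Cyp26b1, an enzyme that degrades RA, was 43.3-fold higher (log2 5.44 ± 0.60, n = 2 arrays per group, adjusted p = 0.0156). Hoxb4 and Hoxb5, homeobox genes with RA response elements, were not well above background without RA and at least 62.0-fold and 12.3-fold higher with it (adjusted p = 0.0039 and 0.0156). Abca1, a cholesterol exporter, was 11.7-fold higher (3.55 ± 0.46, adjusted p = 0.0223). Tgfbi, a matrix protein induced by TGF-beta, was 33.9-fold lower (-5.08 ± 0.37, adjusted p = 0.00786), Pcp4, a calmodulin-binding neuronal peptide, 26.5-fold lower (-4.73 ± 0.28, adjusted p = 0.0039), and Htr3a, a serotonin-gated channel subunit, 11.4-fold lower (-3.52 ± 0.34, adjusted p = 0.0129).

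Among the fixed lists, 3 of 25 RA response genes rose and 1 fell in the parental line (5 and 1 adjusted over the list alone). Rarb, the RA receptor beta gene, was at least 2.7-fold higher, and Stra6, the receptor that imports retinol, was 23.7-fold lower (-4.57 ± 0.47), with only 1 of the 2 parental RA arrays well above background. Camera gave the list an adjusted p of 0.559. The neuronal cytoskeleton list had a median of -0.526, with 2 of 26 members lower (5 adjusted over the list alone), Stmn2 at -2.51 ± 0.35 and Dpysl3, a growth cone collapse mediator, at -1.73 ± 0.28. The camera adjusted p was 0.000125, and adjusted p = 0.293 with an estimated correlation. Of 23 adrenergic neuroblast markers 1 fell, Dbh at -3.07 ± 0.43 (7 adjusted over the list alone; median -0.699, camera adjusted p = 0.000125, and adjusted p = 0.207 with an estimated correlation). Extracellular matrix genes had a median of -0.705, with 1 of 32 lower (11 lower and 1 higher adjusted over the list alone), Fn1, the fibronectin gene, at -1.88 ± 0.29. In the camera test the adjusted p was 4.8e-05, and adjusted p = 0.216 with an estimated correlation. Integrin and actomyosin genes were lower for 3 of 31, including the integrin genes Itgb3 at -3.41 ± 0.38 (1 of the 2 parental RA arrays well above background) and Itgb4 at -1.70 ± 0.28 (3 adjusted over the list alone). For this list camera gave adjusted p = 0.000164, and adjusted p = 0.207 with an estimated correlation. DNA replication genes had a median of 0.519 with 0 of 30 past the test for single genes. Camera gave this list an adjusted p of 4.8e-05, and adjusted p = 0.207 with an estimated correlation. The blood vessel and microglial list was also called (camera adjusted p = 0.0463, and adjusted p = 0.634 with an estimated correlation), with Hba-a1, a globin gene, at -3.19 ± 0.38 and Tmem119, a microglial marker, at -2.25 ± 0.32, as was the fibroblast list with 0 of 10 members past the test (3 lower adjusted over the list alone). Tested by camera, the list had an adjusted p of 0.0342, and adjusted p = 0.291 with an estimated correlation.

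The limma test called 297 of 26247 genes with RA in the parental line, 142 higher and 155 lower. The count was 55 with normexp, 17 with no filter, 635 with only probes above background on all arrays and 803 with a trended and robust variance. It was 1, 0, 0 and 0 without parental RA replicate 1, parental RA replicate 2, parental untreated replicate 1 and parental untreated replicate 2 (3382, 2173 and 3361 genes at an unadjusted p under 0.05 in the cases of 0), 38 without either clone untreated array, and 655 without either clone RA array. Camera called 14 lists, and 7 without parental RA replicate 1 and 9 without parental untreated replicate 1 or either clone RA array. The integrin call ended without parental RA replicate 1 (adjusted p = 0.0634). The blood vessel call ended with quantile normalization (0.071), no filter (0.141), the mean of probes (0.0511), fry (0.289) and without each array except parental RA replicate 2 (0.0507 to 0.26). The fibroblast call ended with no filter (0.0551), with fry (0.0522), and without parental RA replicate 1 (0.247), parental untreated replicate 1 (0.0564) or either clone RA array (0.0507).

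With RA in the clone, Cyp26b1 was higher as in the parental line, and single genes of cell division and of the stress response were lower. Slide row and possibly serum go with RA here. Cyp26b1 was 83.2-fold higher (log2 6.38 ± 0.60, n = 2 arrays per group, adjusted p = 0.0117). Ddit3, the stress transcription factor CHOP, was 8.39-fold lower (-3.07 ± 0.31, adjusted p = 0.0117), Cdkn1a, the cell cycle inhibitor p21, 5.82-fold lower (-2.54 ± 0.35, adjusted p = 0.021), and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, 4.19-fold lower (-2.07 ± 0.31, adjusted p = 0.0232). Nrp1, a semaphorin receptor, was 11.8-fold higher (3.56 ± 0.35, adjusted p = 0.0117) and Plxna4, its plexin partner, 9.34-fold (3.22 ± 0.29, adjusted p = 0.0117). The axon guidance list that holds them went both ways, with 2 higher and 2 lower of 24 (6 and 2 adjusted over the list alone), Slit1 among the lower at -1.89 ± 0.26, and camera gave an adjusted p of 0.31.

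The list of mitotic genes had a median log2 change of -1.40 in the clone with RA, and 13 of its 30 members fell (26 adjusted over the list alone), including the mitotic kinase genes Plk1 at -1.69 ± 0.26 and Aurka at -1.63 ± 0.30. Camera gave an adjusted p of 3.32e-16, and an adjusted p of 0.314 with an estimated correlation. DNA replication genes had a median of -0.565, with 1 of 30 lower, the ribonucleotide reductase gene Rrm2 at -1.39 ± 0.25 (9 adjusted over the list alone). The camera adjusted p was 1.11e-06, and adjusted p = 0.314 with an estimated correlation. Of 27 genes of amino acid starvation and endoplasmic reticulum stress 8 fell (14 lower and 1 higher adjusted over the list alone), among them the glutathione-degrading Chac1 at -2.46 ± 0.26 and the serine synthesis gene Phgdh at -1.80 ± 0.25. The list had a camera adjusted p of 5.64e-07, and adjusted p = 0.314 with an estimated correlation. Nuclear lamina and envelope genes were lower for 2 of 23, Lmna and Syne3, a nesprin gene, at -2.38 ± 0.28 (2 adjusted over the list alone). In the camera test the adjusted p was 0.00152, and adjusted p = 0.314 with an estimated correlation. Adrenergic neuroblast markers rose for 3 of 23 (6 higher and 3 lower adjusted over the list alone), with the granule protein gene Chga at 1.71 ± 0.29 and the transcription factor gene Phox2a at 1.53 ± 0.30. For this list camera gave adjusted p = 0.0449, and adjusted p = 0.476 with an estimated correlation. Mitochondrial respiratory chain genes had a median of -0.679 with 1 of 38 lower, Cyc1 at -1.47 ± 0.28 (camera adjusted p = 1.11e-06, and adjusted p = 0.526 with an estimated correlation), and that median was -0.262 under quantile normalization. The RA response list held 3 higher members and 1 lower of 25 (5 and 2 adjusted over the list alone), with Stra6 at -2.94 ± 0.47, and camera gave an adjusted p of 0.104. Camera also called the list of serum and immediate early genes with RA in the clone, but not in the parental line. The call ended with quantile normalization (adjusted p = 0.0564), with fry (0.0789) and with an estimated correlation (0.486). It also ended without clone RA replicate 1, clone untreated replicate 1 or either parental RA array.

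The limma test called 1216 genes with RA in the clone, 677 higher and 539 lower. The share called higher was 55.7%, against 48.1% with quantile normalization and 40.5% with normexp. The count was 440 with normexp, 1895 with only probes above background on all arrays, 2172 with a trended and robust variance, and 0 with no filter or with only the clone groups fitted (5047 and 5361 genes at an unadjusted p under 0.05). It was 0 without clone untreated replicate 1 or 2 (4092 and 3213 genes at an unadjusted p under 0.05), 267 without either parental untreated array, 477 without clone RA replicate 1 (239 higher and 238 lower) and 3032 without clone RA replicate 2 (2484 higher and 548 lower). Without clone RA replicate 1, called members numbered 0 lower in the mitotic list, 2 lower in the stress list, 1 lower in the lamina list, 0 lower in the replication and respiratory lists and 0 higher and 1 lower in the adrenergic list. The lamina call ended without that array (camera adjusted p = 0.104) and with quantile normalization (0.0934), whereas the RA response list was called without that array (0.00416). The adrenergic call ended with no filter (0.11) and without clone untreated replicate 1 (0.0565) or 2 (0.0611) or clone RA replicate 2 (0.4), and the respiratory call with quantile normalization (0.0934) and fry (0.118).

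Both lines shared part of the RA response, although serum may go with RA in both. Of the genes called in each line, 36 were higher in both, against 3.66 for independent lists, and 35 were lower in both, against 3.18. Shared higher genes included Cyp26b1, the fibrillar collagen gene Col11a2 (4.10 ± 0.29 in the parental line) and Hic1, a transcriptional repressor (1.82 ± 0.29 in the parental line and 1.34 ± 0.29 in the clone). Shared lower genes included Stra6, at -4.57 ± 0.47 in the parental line and -2.94 ± 0.47 in the clone. Opposite calls numbered 5 higher in the parental line and lower in the clone, against 2.92 for independent lists, and 9 the other way, against 4. Both tests used the same estimate of each gene's spread, which favours calls in both lines whatever their direction. The numbers for independent lists may therefore be too low as a level without a shared response. Of the 297 genes called in the parental line 72.1% had the same sign in the clone, and of the 1216 called in the clone 73.2% had the same sign in the parental line. Across all 26247 genes, which are not independent replicates, the RA responses of the lines correlated at r = 0.22 (Spearman's rho = 0.258). This r was 0.0226 with no filter on dim probes.

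**Figure D2:**
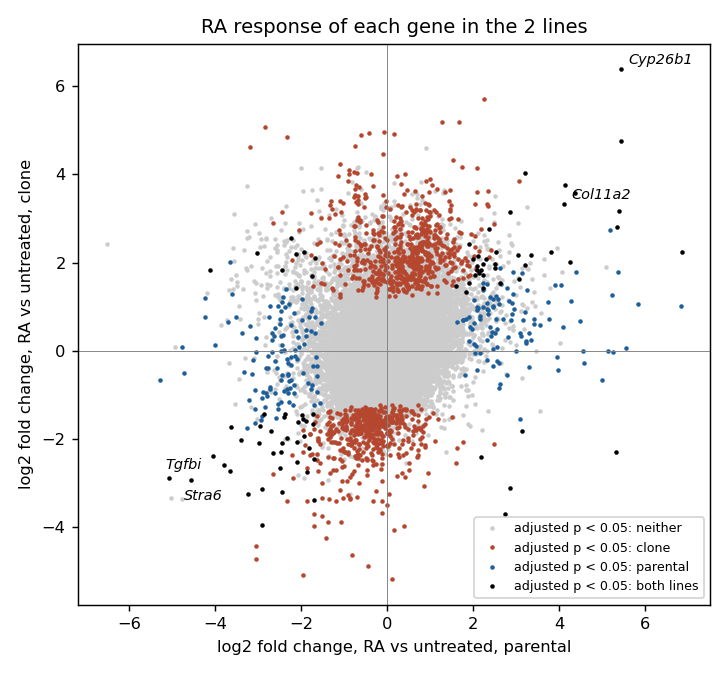
Log2 fold change with RA of each tested gene in the parental line (x axis) and in the clone (y axis); each point is 1 gene, coloured by the line or lines in which its limma adjusted p was under 0.05. Cyp26b1 lay highest in the clone at 6.38 and at 5.44 in the parental line, and Tgfbi and Stra6 were lower in both.

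The clone by RA interaction compares the RA changes of the lines, and slide row cannot be told apart from it. Plxna4, a semaphorin co-receptor, responded higher in the clone by a log2 difference of 4.52 ± 0.40 (n = 2 arrays per group, adjusted p = 0.018), being at -1.30 ± 0.29 in the parental line and 3.22 ± 0.29 in the clone. Ptgds, a prostaglandin D synthase gene, fell in the parental line (-2.25 ± 0.25) and rose in the clone (2.55 ± 0.25), a difference of 4.80 ± 0.35 (adjusted p = 0.0159). Rab3b, a synaptic vesicle GTPase gene, did the same at -1.69 ± 0.27 and 2.11 ± 0.27, a difference of 3.80 ± 0.39 (adjusted p = 0.0322). Genes that responded lower in the clone included Cdkn1a at -4.15 ± 0.49 (adjusted p = 0.0416), Ddit3 at -3.92 ± 0.44 (adjusted p = 0.0383) and Atf3, a stress-induced transcription factor gene, at -3.29 ± 0.39 (adjusted p = 0.0416).

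Of the 54 genes called by the interaction, 32 responded higher and 22 lower in the clone, and in 48 the RA changes of the lines had opposite signs. Among lists, mitotic genes had an interaction median of -1.48, with a median of 0.0185 with RA in the parental line and -1.40 in the clone; 0 of 30 members passed alone and 22 did adjusted over the list alone. Tested by camera, the list had an adjusted p of 2.38e-15, and adjusted p = 0.163 with an estimated correlation. DNA replication genes had a median of -1.04 (0 of 30, and 11 lower adjusted over the list alone). Camera gave this list an adjusted p of 5.74e-13, and adjusted p = 0.163 with an estimated correlation. Genes of amino acid starvation and endoplasmic reticulum stress had a median of -0.662, with 1 of 27 lower (4 adjusted over the list alone). In the camera test the adjusted p was 1.25e-05, and adjusted p = 0.204 with an estimated correlation. Adrenergic neuroblast markers had a median of 1.05 (0 of 23, and 8 higher adjusted over the list alone). The list had a camera adjusted p of 3.17e-06, and adjusted p = 0.163 with an estimated correlation. Cholinergic genes had a median of 1.49 (0 of 15, and 3 higher adjusted over the list alone), which was 0.859 without clone RA replicate 1 and 0.829 with quantile normalization. For this list camera gave adjusted p = 0.000255, and adjusted p = 0.204 with an estimated correlation, and the call ended with fry (0.0629). The cholinergic list was called by camera with RA in the parental line but not in the clone, so its interaction is not by itself a rise in the clone. That parental call ended with fry (0.141). Camera also called the list of serum and immediate early genes by the interaction, a call that ended with fry (0.112) and an estimated correlation (0.328). That call also ended without clone RA replicate 1. Slide row cannot be told apart from this interaction, because row 1 held the parental RA and untreated clone arrays and row 2 the others. The count of 54 was 0 with normexp, with no filter (2449 and 3178 genes at an unadjusted p under 0.05) and without any 1 of 6 arrays: parental RA replicate 1 and 2, clone untreated replicate 1 and 2 and parental untreated replicate 1 and 2 (3695, 3476, 2614, 2435, 2692 and 2920). It was 310 with only probes above background on all arrays, 454 with a trended and robust variance and 21 with the slide side as a block. It was 43 without clone RA replicate 1 (24 higher and 19 lower) and 1002 without clone RA replicate 2 (886 higher and 116 lower), where camera called 10 lists against 16.

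**Figure D3:**
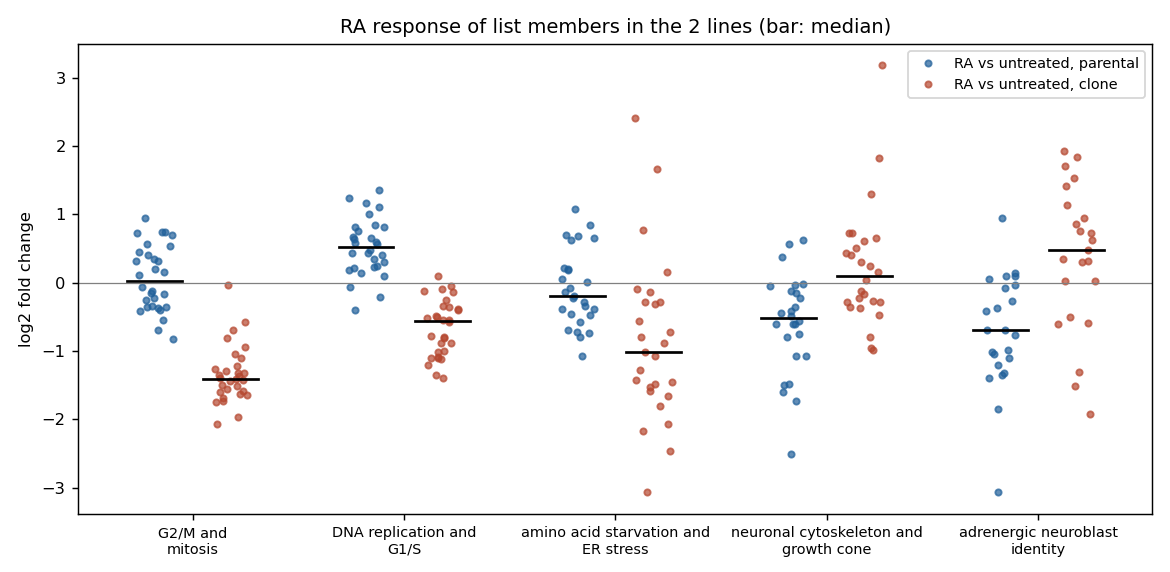
Log2 fold change with RA (y axis) of the members of 5 gene lists (x axis) in the parental line and in the clone; each point is 1 gene and the bar is the median. The mitotic list had a median of 0.0185 in the parental line and -1.40 in the clone.

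Under RA, single genes of neurons were higher and single genes of proliferation and stress lower in the clone than in the parental line. Stmn2 was 138-fold higher in the clone (log2 7.11 ± 0.35, n = 2 arrays per group, adjusted p = 7.88e-05), Scn3a, a neuronal sodium channel gene, 132-fold (7.05 ± 0.37, adjusted p = 9.69e-05), and Sncg, the gamma-synuclein gene, 64.1-fold (6.00 ± 0.39, adjusted p = 0.000194). Npy, the neuropeptide Y gene, was not well above background in the parental line and at least 690-fold higher in the clone (adjusted p = 4.97e-05). Gadd45g, a growth arrest and DNA damage gene, was 580-fold lower (-9.18 ± 0.35, adjusted p = 4.47e-05), Atf3 22.9-fold lower (-4.52 ± 0.28, adjusted p = 0.000165) and Tpx2, a spindle assembly factor gene, 7.42-fold lower (-2.89 ± 0.30, adjusted p = 0.00104).

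By list under RA, 21 of 26 neuronal cytoskeleton genes were higher in the clone and 0 lower (23 and 0 adjusted over the list alone). Tested by camera, the list had an adjusted p of 2.72e-08, and adjusted p = 0.188 with an estimated correlation. Voltage-gated ion channels were higher for 9 of 20 (10 adjusted over the list alone; camera adjusted p = 0.000104, and adjusted p = 0.138 with an estimated correlation), and axon guidance genes for 11 of 24 with 1 lower (13 and 1 adjusted over the list alone). The camera adjusted p was 0.000585, and adjusted p = 0.138 with an estimated correlation. Cholinergic genes were higher for 6 of 15 and lower for 1 (7 and 1 adjusted over the list alone). Ache, which degrades acetylcholine, and Prima1, its membrane anchor, were higher by 3.38 ± 0.35 and 3.51 ± 0.32, and Slc18a3, the vesicular acetylcholine transporter gene, was at -2.03 ± 0.28. The camera adjusted p was 0.0153, and adjusted p = 0.32 with an estimated correlation. Mitotic genes were lower for 24 of 30 (27 adjusted over the list alone), such as the DNA topoisomerase gene Top2a at -2.41 ± 0.29. In the camera test the adjusted p was 5e-13, and adjusted p = 0.158 with an estimated correlation. DNA replication genes were lower for 12 of 30 (21 adjusted over the list alone; camera adjusted p = 9.6e-09, and adjusted p = 0.138 with an estimated correlation), such as Cdc6, an origin licensing factor gene, at -2.04 ± 0.26. Immediate early genes were lower for 14 of 30 and higher for 1 (15 and 1 adjusted over the list alone). In the camera test the adjusted p was 1.49e-06, and adjusted p = 0.158 with an estimated correlation. Extracellular matrix genes went both ways, with 12 higher and 3 lower of 32 (13 and 4 adjusted over the list alone). Timp2, a metalloproteinase inhibitor gene, was at 5.06 ± 0.39 and the basement membrane collagen gene Col18a1 at -4.62 ± 0.37. Camera gave this list an adjusted p of 0.0242, and adjusted p = 0.373 with an estimated correlation. Camera gave adjusted p of 0.593 for Schwann and glial markers, 0.922 for hippocampal neuron markers, 0.58 for blood vessel and microglial markers and 0.0863 for fibroblast markers.

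The limma test called 6084 genes between the lines under RA, 3395 higher and 2689 lower in the clone. The share called higher was 55.8%, against 49.6% with quantile normalization and 49.3% with normexp, and without clone RA replicate 2 the calls were 5053 higher and 2223 lower. The differences of the lines without and with RA correlated at r = 0.697 across genes, and 1240 genes were higher and 721 lower in the clone in both, against 209 and 99.4 for independent lists. Opposite calls numbered 12 and 17, against 165 and 125. A difference made by slide row alone would turn sign between these comparisons, so row does not account for the shared genes, while genes called in only 1 of them were not separated from it. The count was 3650 with normexp, 3703 with no filter, 2639 with only the RA groups fitted and 3823 without parental RA replicate 2. Without clone RA replicate 1, 13 neuronal cytoskeleton genes were called higher. The cholinergic call ended without parental RA replicate 1 (camera adjusted p = 0.0567) and the extracellular matrix call without clone RA replicate 2 (0.063).

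Averaging over treatments sets 4 clone arrays against 4 parental arrays, with both slide rows balanced. Pnma5, a paraneoplastic antigen gene expressed in neurons, was 176-fold higher in the clone (log2 7.46 ± 0.19, n = 4 arrays per line, adjusted p = 7.4e-06), and Prkar1b, a neuronal protein kinase A subunit gene, 172-fold (7.43 ± 0.22, adjusted p = 7.77e-06). Dlk1 was 658-fold lower (-9.36 ± 0.42, adjusted p = 2.42e-05). Lmna was 1.62-fold higher (0.70 ± 0.18, adjusted p = 0.0297), and this call ended with no filter (adjusted p = 0.0783) and without any 1 of the 8 arrays (adjusted p from 0.0508 to 0.114). The neuronal cytoskeleton list was higher for 21 of 26 members (23 adjusted over the list alone; camera adjusted p = 4.73e-08, and adjusted p = 0.228 with an estimated correlation), and the mitotic list lower for 18 of 30 (23 adjusted over the list alone). Camera gave this list an adjusted p of 2.76e-09, and adjusted p = 0.228 with an estimated correlation. Camera called the mitotic list between the lines under RA but not between the untreated lines, and its interaction median was -1.48. The averaged difference of the mitotic list was therefore not shown without RA. In total 7276 genes were called, 4224 higher (58.1%, against 50.2% with quantile normalization and 50.6% with normexp) and 3052 lower. The count was 4457 with normexp, 4702 without clone untreated replicate 1, 4480 without clone untreated replicate 2 and 9062 without clone RA replicate 2 (6043 higher and 3019 lower).

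Averaged over the lines, RA against no RA again sets 4 arrays against 4. Averaging balances slide row but not serum, which may go with RA in both lines. Cyp26b1 was 60.0-fold higher (log2 5.91 ± 0.43, n = 4 arrays per treatment, adjusted p = 0.00525) and Tgfbi 15.8-fold lower (-3.98 ± 0.26, adjusted p = 0.00525). Vim, the vimentin gene, was 2.96-fold lower (-1.57 ± 0.19, adjusted p = 0.0123). Lmna was 1.89-fold lower (-0.92 ± 0.18, adjusted p = 0.0368), a call that ended with normexp (0.0859), quantile normalization (0.0615), no filter (0.116), the slide side as a block (0.0518) and without each array except clone RA replicate 2 (0.0697 to 0.167). Stress genes were lower for 8 of 27 and higher for 1 (14 and 1 adjusted over the list alone; camera adjusted p = 5.28e-05, and adjusted p = 0.475 with an estimated correlation), among them the serine synthesis genes Psat1 at -1.13 ± 0.21 and Psph at -1.18 ± 0.22. Without clone RA replicate 1, 4 of the stress genes were called lower and 0 higher. Camera called the stress list with RA in the clone and by the interaction, but not with RA in the parental line. The average therefore does not show a fall of these genes in both lines. Genes of hypoxia and glycolysis were lower for 2 of 28, Ndrg1, a hypoxia-induced gene, at -2.48 ± 0.30 and Egln3, an oxygen-sensing hydroxylase gene, at -1.28 ± 0.21 (9 lower and 1 higher adjusted over the list alone). The list had a camera adjusted p of 6.46e-05, and adjusted p = 0.348 with an estimated correlation. The average clone effect and the average RA effect correlated at r = 0.0581 across genes (Spearman's rho = 0.167, covariance 0.0463), and at -0.0119 without clone untreated replicate 1. In total 1531 genes were called, 822 higher (53.7%, against 44.7% with quantile normalization and 37.9% with normexp) and 709 lower. The count was 472 with normexp, 120 with no filter and 2435 with a trended and robust variance. Without 1 array it was 309 (parental RA replicate 1), 732 (parental RA replicate 2), 25 (clone untreated replicate 1), 0 (clone untreated replicate 2, with 3940 genes at an unadjusted p under 0.05), 16 (parental untreated replicate 1), 60 (parental untreated replicate 2) and 3205 (clone RA replicate 2, with 2392 higher and 813 lower).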

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

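The test of the clone by RA interaction picked out results for a closer look. It called 54 genes and 16 gene lists. Slide row cannot be told apart from this interaction, so a response particular to a line was not shown. A slide row effect alone would give RA changes of opposite sign in the lines, and 48 of the 54 genes had them. These genes were chosen for a large difference between both RA changes, which favours opposite signs whatever the cause. The count of 48 therefore cannot tell slide row from a response particular to a line. The gene calls all ended with normexp and with no filter, and the list calls with an estimated correlation. Genes that responded higher in the clone were Pdlim3 (4.91), Ptprr (4.80), Ptgds (4.80), Plxna4 (4.52), Dusp26 (4.50) and Rab3b (3.80). Genes that responded lower were Cdkn1a (-4.15), Ddit3 (-3.92), Otog (-3.83), Gzmm (-3.81), Hhipl2 (-3.64), Atf3 (-3.29) and Cxcl10 (-3.15), all on the log2 scale. The weighing tests below were chosen after the results were seen, and the test of other splits of the arrays was chosen before.

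The mitotic list had a median of -1.40 with RA in the clone, with 13 of 30 members lower (26 adjusted over the list alone), and of 0.0185 in the parental line, with 15 members positive and 15 negative. Of its members 0 passed the interaction test, and the list was called there only at the preset correlation (adjusted p = 0.163 with an estimated one). Without the array clone RA replicate 1, the median in the clone was -1.29 and all 30 members stayed negative, which argues against that array as the cause of the direction, although 0 members then passed the test for single genes. Among 10000 random lists matched on brightness, the lowest interaction median was -0.723 against -1.48 for the mitotic list, which argues against slide row acting through brightness. Slide row acting on these genes together with an RA effect alike in both lines could give the same values, with an average RA median of -0.622, and cannot be told apart from a line-specific response. Lower serum may also go with RA, and its part was not tested.

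Chat was not called higher in the untreated clone, although the labels describe the clone as expressing its enzyme. On the first principal component 0 arrays lay on the other line's side, which argues against an array with the other line's label. The 95% interval reached 3.38, so a large Chat difference could be hidden by the spread. With 1 probe on the array, it cannot be told whether that probe reads the transcript of the enzyme in the clone.

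Dim probes were raised on the array clone RA replicate 1. Negative control spots lay 0.697 above the other arrays on the log2 scale and dim probes of like brightness 1.37 above. Negative controls were raised more on parental untreated replicate 1, by 1.08 with dim probes at 0.93, but only on clone RA replicate 1 did dim probes exceed them. These values are scaled to each array's 75th percentile, and a low percentile raises scaled controls. It was 472.1 on clone RA replicate 1 and lowest, at 264.8, on parental untreated replicate 1. Before scaling, the background-subtracted mean of negative controls was -6.414 on clone RA replicate 1, against -3.109 to -1.818 on the others. The 0.697 therefore does not measure background left in the signal alone, and that explanation of the 1.37 stayed open. Probes named by coordinates exceeded mRNA probes by 0.200 there, against -0.085 to 0.123 on the others. In bins of like brightness the medians were 2.04 and 1.9 where the rise was largest. They were 1.65 and 1.24 in the dimmest bin and 0.245 and -0.27 in the brightest. The gap was thus not widest where the rise was largest, and nucleic acid other than mRNA could be neither shown nor excluded. No biological explanation was tested.

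Other splits of the arrays into 4 and 4 were fitted with the other factor as a covariate. This fit had no interaction term, unlike the fit with 1 mean per group. Its counts for the real splits therefore differ from the 7276 genes called for the clone average and the 1531 for the RA average. For the clone average, 1 of 34 splits reached its 6281 genes, the real one, and the highest other gave 0. For the RA average, 1 of 34 reached its 504 genes, the real one, and the highest other gave 4, the split by slide row. In the other splits the real difference stayed in the residual spread, which lowers their counts. Those counts therefore do not show how many genes would be called among arrays without a real difference.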

How the results depend on the processing

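With normexp on the median signal, added after the data were seen, the counts of called genes were 1213 (clone against parental, untreated), 55 (RA, parental), 440 (RA, clone), 3650 (clone against parental, RA), 0 (interaction), 4457 (clone average) and 472 (RA average). With no filter on dim probes they were 1386, 17, 0, 3703 and 0 for the first 5 and 120 for the RA average. With only probes above background on all arrays they were 635 (RA, parental), 1895 (RA, clone) and 310 (interaction), and with a trended and robust variance 803, 2172, 454 and, for the RA average, 2435. With only the groups compared, 0 (RA, clone) and 2639 (clone against parental, RA) were called, and with the slide side as a block 21 by the interaction. Leaving out 1 array at a time, where the lone array is assumed to vary like the other groups, gave 786 to 3174, 0 to 655, 0 to 3032, 3823 to 7276, 0 to 1002, 4480 to 9062 and 0 to 3205 genes in the same order. Lists called were 0 in all 7 comparisons with an estimated correlation, and 9 (RA, parental), 9 (interaction) and 17 (clone average) with fry. Leaving out arrays gave 3 to 7, 7 to 15, 8 to 12, 10 to 16, 10 to 17, 8 to 14 and 8 to 10 lists. The correlation of the average effects was 0.129 with no filter and -0.0119 to 0.182 without 1 array. That of the RA effects in both lines was 0.132 with normexp, 0.157 with quantile normalization, 0.0226 with no filter, 0.307 with the stricter filter and 0.16 to 0.234 without 1 array. Chat in the untreated clone turned to -0.06 with normexp and ran from -0.59 to 1.35 without 1 array, turning without clone untreated replicate 2 (-0.13) and parental untreated replicate 2 (-0.59). Chat with RA in the parental line ran from -1.51 to 0.43, turning without parental RA replicate 2 (0.38) and parental untreated replicate 1 (0.43). The cytosolic ribosomal protein list with RA in the clone turned direction under quantile normalization (adjusted p = 0.934). Fewer arrays leave fewer degrees of freedom and no filter adds dim probes, and otherwise the cause was not tested. Of 77 list calls, 60 stayed the same under quantile normalization, 69 with no filter, 70 with the mean of probes and 56 with fry. Named genes called under every alternative and kept by the stricter filter numbered 35 of 65, 0 of 24, 0 of 49, 79 of 99, 0 of 13, 81 of 96 and 0 of 41, and 0 called genes turned direction. No paired analysis by culture was possible because the labels do not say which arrays share one, and the fit with the slide side as a block served as a block by replicate number. The planned normexp correction on the mean signal was not run. Signal over background on the array clone RA replicate 1 (71.7% of probes, against 47.74% to 62.76%) limits the dim genes.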

Other observations

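Hprt, which salvages purines and is the enzyme lost in thioguanine-resistant lines, was 12.0-fold higher in the untreated clone than in the untreated parental line (log2 3.58 ± 0.34, n = 2 arrays per group, adjusted p = 0.00113). Mean log2 scaled intensity was 1.53 ± 0.01 (SD) in the parental line and 5.11 ± 0.12 in the clone. Averaged over treatments the difference was 3.08 ± 0.24 (adjusted p = 0.000187).

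Among neurotrophin receptors and ligands, 3 of 19 genes were higher and 2 lower in the untreated clone (6 and 3 adjusted over the list alone), and camera gave an adjusted p of 0.972. The lower genes were Artn, the artemin gene, 28.4-fold lower (log2 -4.83 ± 0.34, 1 of the 2 clone arrays well above background, adjusted p = 0.000449) and Bdnf, a survival factor of neurons, 16.2-fold lower (-4.02 ± 0.30, adjusted p = 0.000484). Interferon response genes went both ways with RA, with 0 higher and 1 lower of 21 in the parental line (3 and 5 adjusted over the list alone, camera adjusted p = 0.0802) and 2 higher and 2 lower in the clone (2 and 3 adjusted over the list alone, camera adjusted p = 0.868). Oas1a, an interferon-induced antiviral gene, was 12.7-fold lower with RA in the parental line (-3.66 ± 0.40, adjusted p = 0.0156) and 6.56-fold lower in the clone (-2.71 ± 0.40, adjusted p = 0.0225), where its relatives Oasl1 and Oasl2 were higher by 2.98 ± 0.35 and 2.26 ± 0.38.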
